A study of Mus musculus with 7 samples.

How the data were processed

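DNA methylation was measured in 7 samples of mouse (Mus musculus, strain C57BL/6) on a custom Illumina GoldenGate array, in which bisulphite-converted DNA is extended and ligated at each chosen CpG by allele-specific oligonucleotides for the methylated and the unmethylated state and read in Cy3 and Cy5. Per the labels' protocols, genomic DNA was extracted with phenol and labelled by the manufacturer's procedure. Of the 7 arrays, 5 are titled Met with the numbers 0, 25, 50, 75 and 100 and carry the tissue label DNA, and 2 carry the tissue label brain and are titled A2B5_mas and PSA-NCAM_mas. The numbers were read as nominal percent methylation of graded control DNA, which the labels do not spell out. A2B5 is a ganglioside epitope of glial progenitors and PSA-NCAM is the polysialylated neural cell adhesion molecule of migrating neuroblasts. The labels do not say how these samples were isolated, from which brain region they came, what the ending of their titles means, or the sex of the animals.

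The authors deposited 1 table of 382 probes by 7 arrays. Its values were taken as methylation fractions (beta values, from 0 for unmethylated to 1 for methylated), because every deposited value lay between 0.0282 and 0.972 and 0 were missing. The software, background correction, normalization between arrays, probe filters and genome build are not given in the sources used here, and no intensities or detection p-values were used. A background left in the signal, or a scaling applied between arrays, could change the beta values and the differences between arrays. Depth has no meaning for this array, and its precision is limited by the number of arrays, which was 1 per group. No replicate spread could therefore be computed, and differences between arrays carry no p-value.

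Each probe ID begins with a gene symbol followed by a number whose meaning is not stated. The symbols, 381 different ones, were looked up in a RefSeq gene table of the mouse assembly GRCm38.p6. Of the 382 probes, 362 carried a current symbol and 20 an older name of 1 current gene, and 0 had no match. Of the current symbols, 11 are also older names of another gene, among them Gje1, Cnr1 and Cnr2, so these names are uncertain. No coordinates are given because the position of the measured CpG is not stated.

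All computations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scikit-learn 1.9.0, and plots with matplotlib 3.10.9. The median beta value of each Met array was regressed on the number in its title, and the slope was compared with all 120 orders of the 5 arrays in an exact two-sided permutation test, whose smallest possible p is 0.0167. A probe was called responsive when its beta value in Met_100 exceeded that in Met_0 by at least 0.3. The brain arrays were compared on responsive probes by a fixed rule of size, a difference of at least 0.2. Levels were classed as low under 0.2, intermediate from 0.2 to 0.8 and high over 0.8. Array error was described by the SD of each probe's Met values around a straight line and, chosen after seeing that this line was strongly bent, by the departure of Met_50 from the line between Met_25 and Met_75. The latter gave a root mean square SD of 0.0231 per array over responsive probes (median 0.0151), and 0.0326 for a difference of 2 arrays. It also holds any real bend of a probe's curve between these arrays and any mixing error. As an alternative scale, each brain value was read off its probe's own Met curve, made monotone by isotonic regression and linear between points. Values below Met_0 read as 0.

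The 12 gene lists were fixed before the data were examined. They were imprinted, neuronal, astrocyte and oligodendrocyte, neural stem and progenitor, homeobox and patterning, pluripotency, germline, microglia and blood, endothelial, cancer-related promoter, neurotransmission and stress, and DNA methylation and chromatin genes. The median difference of each list with at least 3 responsive probes was placed among 10000 random lists of the same size matched on level in 5 bins, as a description of these 2 arrays. The genes named were set by a rule fixed at the same time: the 12 responsive probes with the largest and the 12 with the smallest difference, list members differing by at least 0.2, the imprinted members, and the 5 probes with the largest and the 5 with the smallest rise in the Met series. Names outside this rule are marked where they appear, and 1 gene that the rule selects is not reported here, nor drawn in the figure of the lists, though the list counts and medians include it. The code of the rules was checked on simulated data for the 382 probes: all 325 truly responsive probes were called, as were all 30 probes raised by 0.3 and 0 of 30 raised by 0.1. The simulated sizes lay clear of the limits and the simulated Met series was a straight line. These outcomes check the computation only and give no error rates for the real arrays. Alternatives covered the size that counts as responsive or different, the probes used, the summary, the scale, normalization of the brain arrays, 1 value per gene, and leaving out each Met array.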

Results

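The data comprised beta values of 382 CpG probes, nearly each from a different gene, on 7 GoldenGate arrays of mouse DNA. The probed genes are mainly receptors for neurotransmitters, hormones and neuropeptides, together with myelin, hearing and signalling genes. The Met arrays, titled 0, 25, 50, 75 and 100, were read as a graded series of control DNA. The remaining 2 arrays hold brain DNA, titled A2B5_mas after a glial progenitor epitope and PSA-NCAM_mas after a neuroblast marker. Each title stands for 1 array with no replicate, so only the trend over the Met series could be tested.

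The Met series asks how the array's readout follows the number in the title, read here as nominal percent methylation. The median beta value over all 382 probes rose in every step, from 0.131 in Met_0 to 0.541 in Met_25, 0.608 in Met_50, 0.667 in Met_75 and 0.820 in Met_100. The slope was 0.602 ± 0.145 (SE of the straight line, n = 5 arrays) over the full series, with an exact two-sided permutation p = 0.0167, the smallest that 5 arrays allow. The test treats the arrays as separate samples, and whether they were mixed from the same pair of DNAs is not stated. The rise was uneven. Met_25 already covered 59.5% of the distance between the medians of Met_0 and Met_100, and Met_50 and Met_75 covered 69.3% and 77.9%. Without Met_0 the slope was 0.358, so this array alone decided much of its size.

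Single probes followed the same course. Of the 382 probes, 304 were higher at each of the 4 steps, against 3.18 expected on average from random orders. All probes were read on the same Met arrays and are not independent, so this comparison adds no evidence to the test of the medians. Responsive probes, with a beta value in Met_100 at least 0.3 above that in Met_0, numbered 331 (86.6%). Without Met_0, and with the required rise scaled to the shorter series, 212 probes met the rule. The largest differences between the end arrays were those of Strc (stereocilin of the inner ear hair bundle), with 0.0451 in Met_0 and 0.961 in Met_100, and of Adra1a (an adrenergic receptor), with 0.0319 and 0.936. F2rl2, a protease-activated receptor, had 0.0418 and 0.939, Chrna9, a nicotinic receptor subunit of hair cells, 0.0648 and 0.961, and Ush1g, an Usher syndrome gene, 0.0354 and 0.921.

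A small set of probes ran the other way. The 5 smallest differences belonged to Chrm1 (the muscarinic receptor M1), Fbxo11, Nkx6-2 (a homeobox factor of oligodendrocytes), Ppp3cb (a calcineurin subunit) and Ptgdr (a prostaglandin D receptor). Each of these was lower at every step of the series, and no other probe was. Chrm1 had 0.833 in Met_0 and 0.498 in Met_100, Fbxo11 0.251 and 0.0336, and Nkx6-2 0.942 and 0.824. Of the 51 probes that were not responsive, 24 had a beta value of at least 0.4 in Met_0 and 17 stayed under 0.4 in Met_100.

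**Figure D1:**
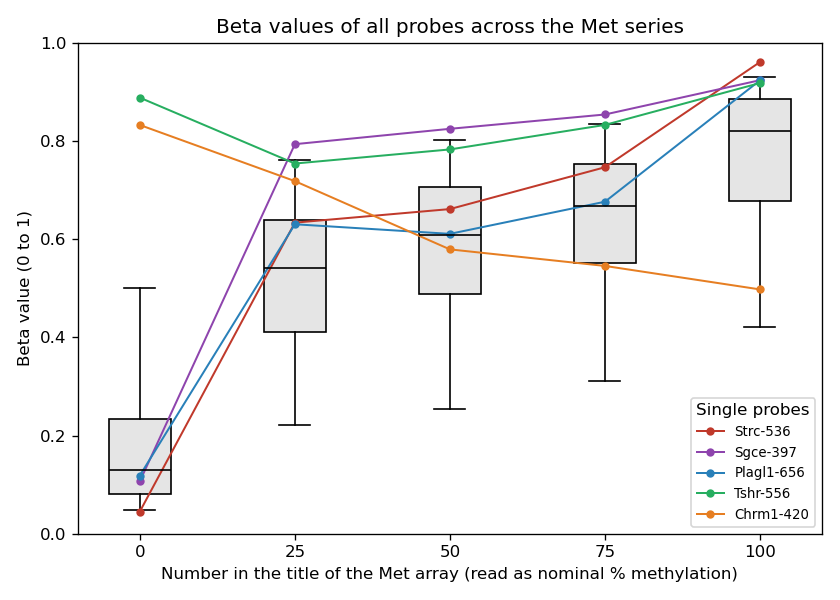
Beta value (vertical axis, 0 to 1) against the number in the title of each Met array (horizontal axis, read as nominal percent methylation). Boxes give the quartiles and median of all 382 probes with whiskers from the 5th to the 95th percentile, and coloured lines follow 5 single probes. The median moves from 0.131 to 0.541 between Met_0 and Met_25 and by less at each later step, Chrm1 is lower in Met_100 (0.498) than in Met_0 (0.833), and Tshr starts at 0.889.

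The brain arrays were mostly unmethylated at these CpGs. Among the 331 responsive probes, A2B5_mas had 68.6% low (under 0.2), 26.9% intermediate and 4.53% high (over 0.8), and PSA-NCAM_mas had 71.9% low, 25.4% intermediate and 2.72% high. Met_0 had 73.4% low and Met_100 60.7% high by the same limits. The class was the same in both brain arrays for 312 of the 331 probes, with 226 low in both. The 9 probes high in both, listed after their values were seen, were Strc at 0.972 in A2B5_mas and 0.971 in PSA-NCAM_mas, Ppp2r5c (a phosphatase subunit) at 0.943 and 0.947, Drd3 (a dopamine receptor) at 0.926 and 0.909, Lep (leptin) at 0.889 and 0.860, Tert (telomerase) at 0.887 and 0.814, and Chrna9, Glp2r, Nmur1 and Brs3.

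The imprinted list had 3 probes on the array. Sgce (epsilon-sarcoglycan, expressed from the paternal allele) had a beta value of 0.583 in A2B5_mas and 0.578 in PSA-NCAM_mas. Plagl1 (a zinc finger factor, also paternally expressed) had 0.448 and 0.444. Calcr (the calcitonin receptor, imprinted in brain) had 0.141 and 0.118. Read off their own Met curves, Sgce stood at 17.3% and 17.2% and Plagl1 at 16.4% and 16.2%, since both probes had passed 0.6 in Met_25. How far these CpGs lie from the imprinted control regions is not stated.

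The values of Met_0 were not uniformly below the brain values. The beta value was under that of Met_0 at 191 of the 331 responsive probes (57.7%) in A2B5_mas and at 195 (58.9%) in PSA-NCAM_mas. Over all 382 probes, 26 were at least 0.2 higher in Met_0 than in both brain arrays and 57 were at least 0.2 lower. Examples of the former, chosen after their values were seen, were Tshr (the thyrotropin receptor), with 0.889 in Met_0, 0.0925 in A2B5_mas and 0.0780 in PSA-NCAM_mas, Bdnf (the neurotrophin), with 0.441, 0.0622 and 0.0472, and Olig2 (an oligodendrocyte lineage factor), with 0.431, 0.0750 and 0.0735.

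A2B5_mas and PSA-NCAM_mas were then compared with each other, a contrast of material titled after a glial and after a neuronal progenitor marker. Of the 331 responsive probes, 0 differed by 0.2 or more in either direction, and the same held for all 382 probes. This rule is coarse for the array. Between Met_50 and Met_75 the responsive probes had a median absolute difference of only 0.0579. The count of 0 therefore does not show that the 2 samples have the same methylation. Over the responsive probes the differences ran from 0.0955 lower to 0.114 higher in A2B5_mas, with a median of 0.00370, and over all 382 the largest absolute difference was 0.127. The median absolute difference of the responsive probes, of which 226 were low in both arrays, was 0.0101, and Pearson's r across the 382 probes, which are not independent replicates, was 0.994. With 1 array each there was no test, and these values describe the 2 arrays only. On the scale of the Met curves 9 responsive probes were at least 0.2 higher in A2B5_mas and 0 lower. On that scale 185 of the 331 read 0 in both arrays and could not differ.

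The differences were not spread evenly over the range. Of the 49 responsive probes with a mean beta value from 0.4 to 0.8, 46 were higher in A2B5_mas, with a median difference of 0.0591 and an SD over probes of 0.0330. Of the 178 probes with a mean under 0.1, 89 were higher, with a median difference of -6.1e-05. From 0.1 to 0.2, 36 of 53 were higher (median 0.00695), and from 0.2 to 0.4, 32 of 42 (median 0.0243). From 0.8 to 1, 8 of 9 were higher (median 0.0289). At a size of 0.05, a limit chosen after the data were seen, 38 responsive probes were higher in A2B5_mas and 3 lower. The middle Met arrays gave an SD of 0.0326 for a difference of 2 arrays. That SD describes single probes and cannot size a shift common to many probes of an array.

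Among responsive probes the largest difference towards A2B5_mas was at Gje1, a connexin whose symbol has named more than 1 gene, with 0.615 in A2B5_mas and 0.501 in PSA-NCAM_mas, a difference of 0.114. Cnr2 (a cannabinoid receptor) had 0.449 and 0.340, Dld (dihydrolipoamide dehydrogenase) 0.474 and 0.367, and the ATP-gated channels P2rx7 and P2rx1 differed by 0.104 and 0.101. Gfap (the astrocyte intermediate filament) had 0.640 and 0.549, a difference of 0.0917. Edg8, now S1pr5, a sphingosine 1-phosphate receptor of oligodendrocytes, differed by 0.0862. Other members of this set were Pthr1 (now Pth1r), P2ry4, Tbxa2r and Cacna1d, with differences from 0.0815 to 0.0962.

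In the other direction the largest difference among responsive probes was at Spnb4, now Sptbn4, the spectrin of axon initial segments and nodes of Ranvier, with 0.294 in A2B5_mas and 0.390 in PSA-NCAM_mas. Dusp5 (a MAP kinase phosphatase) had 0.0941 and 0.156, Gal3st1 (the enzyme that makes sulfatide) 0.183 and 0.233, and Mme (neprilysin) 0.142 and 0.190. Mef2a, Hrh3, Lypd1, Npffr2, Gabra2, Gnpat, Fshr and Sstr3 made up the rest, from 0.0257 to 0.0418 lower in A2B5_mas. From Npffr2 to Sstr3 the differences were smaller than the SD of 0.0326 given by the middle Met arrays. Those arrays had medians from 0.552 (Met_25) to 0.685 (Met_75) over responsive probes. Of these brain probes only Fshr reached such levels, so the SD may not apply to the rest. Among responsive probes with a mean under 0.1, such as Gnpat, the brain difference had an SD over probes of 0.00892.

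**Figure D2:**
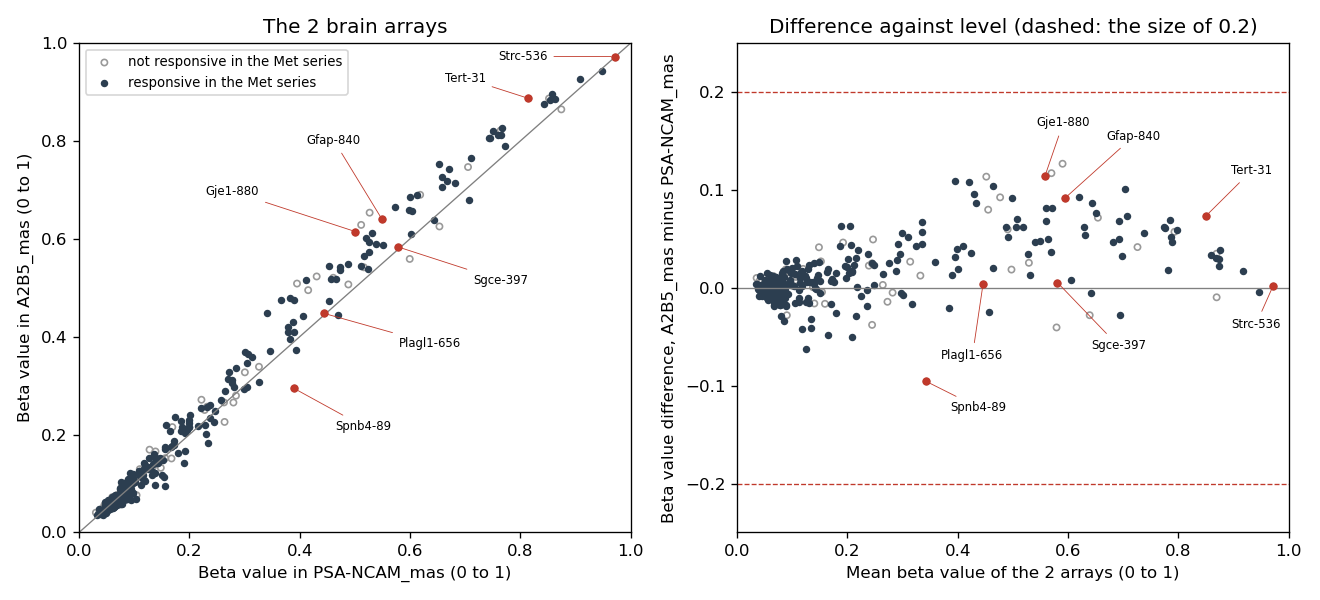
Left, beta value in A2B5_mas (vertical) against PSA-NCAM_mas (horizontal) for all 382 probes, with the line of equality; right, the difference A2B5_mas minus PSA-NCAM_mas (vertical) against the mean of both arrays (horizontal), with dashed lines at a size of 0.2; filled points are responsive probes, open points the others, and red points the labelled ones. Points lie within the dashed lines throughout, and 46 of the 49 responsive probes with a mean from 0.4 to 0.8 lie above 0. Sgce and Plagl1 are among these 46 and lie close to 0, as do some probes outside the imprinted list.

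No member of the fixed lists differed by 0.2, so the list members named from here on, apart from those already among the furthest probes, were chosen after their values were seen. The astrocyte and oligodendrocyte list had 6 responsive probes, 4 higher and 2 lower in A2B5_mas. Its median difference was 0.0320, at the 93.9th percentile of 10000 random lists matched on level. Gfap had 0.640 and 0.549 and Gm98 (now Myrf, the myelin regulatory factor) 0.236 and 0.173, while Mbp (myelin basic protein) had 0.0549 and 0.0647, Olig2 0.0750 and 0.0735, and Slc1a3 (an astrocyte glutamate transporter) 0.234 and 0.237. With its 3 unresponsive probes included, the list's median difference was 0.00147.

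The neuronal list had 4 responsive probes, 1 higher and 3 lower in A2B5_mas, with a median difference of -0.00506 at the 12.8th percentile. Ncam1, the protein that carries polysialic acid, had 0.0741 in A2B5_mas and 0.0791 in PSA-NCAM_mas, and Camk2a had 0.0642 and 0.0742. The neural stem and progenitor list had 9 responsive probes, 8 of them low in both arrays, with Hes1 the lowest at 0.0361 and 0.0324, while Sox2 had 0.207 and 0.184. Its median difference was 0.00445, at the 89.9th percentile. The neurotransmission and stress list had 21 responsive probes, 16 higher and 5 lower, with a median difference of 0.00289 at the 62.3rd percentile, and 18 of them were low in both arrays. The exceptions were Drd3, Gabra2 and Htr2c (a serotonin receptor), the last with 0.442 and 0.406.

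The pluripotency list (Myc, Sox2 and Tert) had a median difference of 0.0224 at the 73.1st percentile, and the imprinted list one of 0.00527 at the 8.84th percentile. The remaining lists had too few probes for a percentile. Among the homeobox and patterning genes, Pax3 and Tbx1 had differences of 0.00231 and 0.0175. Single probes of the lists for other cell types were Ifng (interferon gamma) for blood cells, with 0.609 in A2B5_mas and 0.601 in PSA-NCAM_mas, and Ednrb (an endothelin receptor) for endothelium, with 0.120 and 0.108. The cancer-related list held only Cdkn1b, with 0.0517 and 0.0604, and the germline and the DNA methylation and chromatin lists had 0 probes on the array.

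**Figure D3:**
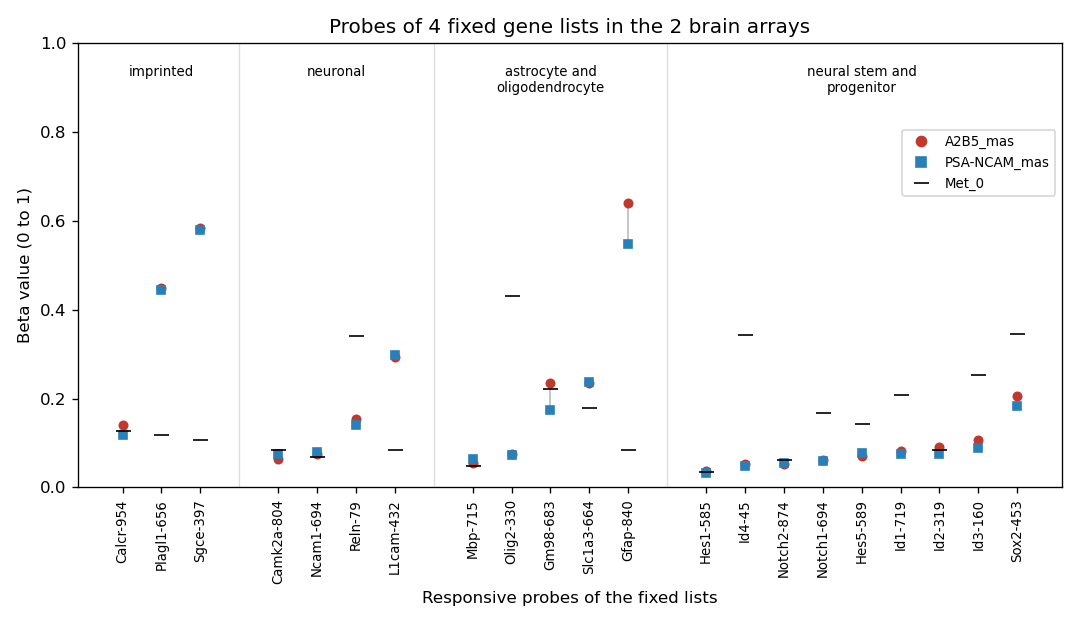
Beta value (vertical axis, 0 to 1) of responsive probes (horizontal axis) of 4 gene lists fixed before the data were examined, in A2B5_mas (circles), PSA-NCAM_mas (squares) and Met_0 (dashes). Sgce and Plagl1 lie near the middle of the range in both brain arrays, 8 of the 9 neural stem and progenitor probes are low in both, and Gfap shows a gap of 0.0917.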

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

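The values were recomputed as 76 alternative values of 17 results. For 36 of these the outcome was fixed or nearly fixed by construction, as for a median difference smaller than its yardstick. Of the other 40, 24 stayed within the yardstick of the main value: the permutation test for the Met trend, its SE of 0.145 for the slope with 1 Met array left out, a factor of 1.5 for counts, the 95% Wilson interval over probes for shares, and 0.0326 for differences of beta values. The Met trend had p = 0.0167, the smallest possible, in an exact permutation test with the mean in place of the median. The log2(value / (1 - value)) scale keeps the order of the medians, so the same p in that test was fixed. Responsive probes, chosen for their rise, do not test the trend either. Leaving out each Met array gave slopes from 0.358 (without Met_0) to 0.681 (without Met_25), with too few orders left to reach 0.05. The count of responsive probes, 331, ranged from 248 to 349 under the other alternatives and was 212 without Met_0, which was added after seeing the data. The 0 probes higher in A2B5_mas became 5 at a size of 0.1, 38 at 0.05 (added after seeing the data) and 9 on the scale of the Met curves, where the flat stretch between Met_25 and Met_75 widens small differences. The 0 lower probes became 3 at 0.05. Subtracting the median difference, quantile normalization and all probes left both counts at 0. For the first and the last this was fixed, since the largest absolute difference over all probes was 0.127 and the median difference 0.00370. With limits of 0.3 and 0.7, low probes made up 77.3% in A2B5_mas and 78.2% in PSA-NCAM_mas, intermediate ones 15.7% and 16.3%, and high ones in PSA-NCAM_mas 5.44%. On the scale of the Met curves, where values below Met_0 read as 0, these were 83.7% and 84.9%, 9.37% and 9.97%, and 5.14%. The medians of the 6 lists were all smaller than the yardstick, which therefore does not test them. Under their 24 alternatives 21 kept their sign and 3 became 0. Several of these repeat the main value by construction, since nearly each probe has its own gene and some lists held only responsive probes. The count of kept signs is therefore no measure of stability. The median of the astrocyte and oligodendrocyte list went from 0.0320 to 0.00147 with all probes. With 1 array per title no replicate could be left out of the brain comparison. Its array error could be gauged only from the Met series, where curve bend and mixing error are not separated from it.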

Other observations

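The tests in this part were chosen after the values were seen, except the regression of the Met arrays on the brain arrays. Probes were grouped into families by symbol after the probe names were seen, and the families were not tested against each other. The 21 responsive glutamate receptor probes had a median of 0.0779 for the mean of both brain arrays, with 19 of them under 0.2, and the 17 GABA receptor probes had 0.0890. The 7 acetylcholine receptor probes, among them Chrna9, had 0.358, at the 98.2nd percentile of random sets matched on Met_0, and the 22 inner ear and deafness probes, led by Strc, had 0.190, at the 98.8th percentile. The 13 probes with purine receptor symbols stood at 0.276 (95.7th percentile) and the 7 Notch pathway probes at 0.0600 (4.19th percentile). P2ry5 in the purine set, named outside the rule, now has the symbol Lpar6, so that set follows the older symbols. Of 18 families examined, 2 lay outside the central 95% of their random sets, against 0.9 expected by chance, and Chrna9 belongs to both.

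The 15 responsive X-linked probes, named from textbook knowledge of the genes, had a median of 0.289 in A2B5_mas and 0.264 in PSA-NCAM_mas, against 0.0852 and 0.0871 for the other 316. Their median in Met_0 was also higher, 0.215 against 0.117, and matched on Met_0 the X-linked median lay at the 97.4th percentile of random sets. Intermediate values in both brain arrays were found at 7 of the 15 (46.7%) and at 70 of the other 316 (22.2%), a share at the 94.6th percentile of random sets matched in the same way. Both values are inside the central 95%, so a higher level at X-linked probes stays open.

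The steep rise between Met_0 and Met_25 affects how any beta value on this array is read. A single preference of the assay for methylated template would give the same odds preference at every mixture. The medians of the 331 responsive probes imply 4.62 at 25 and 1.28 at 75, a ratio of 3.62 (95% bootstrap interval over probes 3.33 to 4.11). Each mixture is 1 array, so the interval holds no mixing or array error. The ratio argues against one preference as the whole cause only if the mixtures are as titled, which single arrays cannot show. An unmethylated partner with the methylation of the brain samples would raise Met_25 where the brain arrays are methylated. With Met_0 and Met_100 held fixed in a linear fit the coefficient at 25 was -0.0571 (interval over probes -0.111 to -0.00449). It was -0.0425 at 50 (-0.0928 to 0.0073) and -0.0380 at 75 (-0.0809 to 0.0042). The rise that such a partner would give was thus not seen. These intervals hold no array error and the curves are bent, so this argues against such a partner only within the linear fit. Middle mixtures with more methylated DNA than titled may also have this effect: Sgce and Plagl1, close to 0.5 by beta value, read 16.8% on average off their Met curves, but 2 probes whose distance from the imprinted control regions is not known leave this open. No biological explanation was tested, since these arrays were read as control DNA, which the labels do not spell out.

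The higher values of A2B5_mas at responsive probes with a mean from 0.4 to 0.8, 46 of 49, may be technical or biological. A constant gain of the methylated signal on one array would, without background, shift the log2 odds equally at all levels. The shift was 0.39 at means from 0.4 to 0.8 and 0.13 from 0.1 to 0.4, a gap of 0.25 (95% bootstrap interval over probes 0.16 to 0.35). Probes with a mean from 0.8 to 1, 8 of 9 higher in A2B5_mas, were not part of this test. Background correction is not stated and a background would matter most at low levels, so the gap leaves such a gain open. Any other array difference that depends on level would move imprinted probes too, yet Sgce and Plagl1 differed by 0.00439 on average, against a median of 0.0610 for the other 47 probes, and 1.67% of pairs of those probes had so small a mean difference. With 2 imprinted probes and 1 array per sample, a level-dependent array effect and a difference between the cells cannot be told apart, and a difference specific to astrocyte and oligodendrocyte genes also stays open, since 6 probes at the 93.9th percentile of level-matched lists do not decide it.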
